A study of Homo sapiens with 43 samples.

How the data were processed

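Chromatin immunoprecipitation followed by sequencing (ChIP-seq) was performed in lung squamous cell carcinoma cell lines for H3K27ac, a histone mark of active promoters and enhancers, and for the transcription factors Sox2, Brn2 and p63. Per the labels' protocols, chromatin for H3K27ac, Sox2 and p63 was cross-linked with formaldehyde and sonicated, whereas chromatin for Brn2 was cross-linked with disuccinimidyl glutarate and formaldehyde and digested with micrococcal nuclease before sonication, so that Brn2 lists and the other lists come from different preparations. The labels name 43 samples, of which 27 have a peak list, 1 list per sample. The other 16 are input samples and were not analysed here.

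Each deposited list holds the chromosome, start, end and name of every peak and a score per peak, and the score is the authors' own value. The peak names begin with MACS, the name of a peak caller. Its version, its threshold and the use of the inputs are not given in the sources used here. The scores started at 50 in the lists with the lowest values, and no header says how they were scaled, so they served only to rank peaks within a list. Reads were aligned with Bowtie2 to hg19 (GRCh37), per the submitters' processing notes, which give no version. The files hold no read counts, so the sequencing depth of every library is unknown. The number of peaks and the covered length then stand for how much was called, not for depth, and a shallower or noisier library lists fewer peaks. Coordinates are 1-based and on hg19.

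Peaks on chromosomes 1 to 22 and X were used. Of all peaks, 2092 of the 652792 deposited peaks lay elsewhere and were left out. The line was the unit of replication. The H3K27ac libraries of LK2 and NCI-H520, 2 for each line, were averaged to 1 value per line, and every other list is a single library. The labels do not say that any libraries came from separate cultures, so p-values measure only the spread between these samples, which may be technical. Lines were grouped by the ChIP experiments that the labels list for them. Set A holds the 2 lines with Sox2 and Brn2 ChIP (LK2 and NCI-H520), set B the 3 lines with Sox2 and no Brn2 ChIP (HCC95, KNS62 and HCC2814), and set C the 8 lines with H3K27ac ChIP alone (HARA, LC-1/SQSF, HCC2450, SQ-1, Calu-1, EBC-1, NCI-H2887 and HCC2279). The sets therefore say what was measured, and not which factors a line expresses. Codes in the sample descriptions that could mark a sequencing run were shared by at most 2 libraries, too few for a comparison within a run.

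Similarity of lists was the Jaccard index of covered base pairs, the shared length divided by the combined length. For H3K27ac the index of LK2 with NCI-H520 was ranked among all 78 pairs of the 13 unmodified lines, and the mean index within set B among all groups of 3 lines. For Sox2 the mean index within sets minus that between sets was ranked among the 10 splits of the 5 lines into 2 and 3. Peaks were called shared with an overlap of 1 bp. Shares of peaks carry Wilson 95% intervals, which cover counting error only. Brn2 and p63 peaks were compared with Sox2 peaks, with the same share of the line's H3K27ac peaks (replicate 1) and with 1000 circular shifts of the peaks along their chromosomes as background. For each factor list, the share of sites acetylated in a line was divided by the share of all merged H3K27ac regions acetylated in that line, and sets were compared by two-sided exact permutation tests over lines, with Benjamini-Hochberg adjustment over the 20 tests. LK2_DNp63 was compared with LK2_GFP by kept, lost and gained peaks, with LK2 as a further library of the same background. There was 1 library per arm, so the arms were not tested against each other.

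The planned unit for H3K27ac was the gene with its flanks. No annotation or genome of the files' build was used here, so genes were replaced by fixed bins of 50 kb, a choice made after the files had been seen, and bins are given by coordinates without gene names. Tests of gene lists, motif shares and alternatives that need transcription starts were not run for the same reason. The rest of the plan for genes was kept for bins. The covered length per bin was scaled to an equal total per library, so that a scaled length can exceed the bin, and log2(scaled length + 1000 bp) was tested with limma in 1 fit of the 3 sets, with a mean-variance trend, over bins with a mean of at least 2000 bp. The adjusted p (Benjamini-Hochberg) had to be under 0.05. A log2 difference understates the change of bins with little covered length. Set A was also tested against the 11 other lines, and this fit was repeated for every pair of lines. Regions found in every line of a set and in no other line, the factor peaks inside region and bin classes, and the behaviour of set bins in LK2_DNp63 were added after the files had been seen. For the last, the mean difference between LK2_DNp63 and LK2_GFP was set beside 10000 random lists of bins, which compare bins within 1 library per arm. It was repeated on bins called without LK2. H3K27ac peaks cut to the median length of Brn2 peaks were a further background for Brn2, added after the shares had been seen.

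Named bins follow the rule written for genes before the data were examined, carried over to bins: the 10 higher and 10 lower bins with the largest log2 difference among those past the threshold whose lines did not overlap between the sets, 1 bin from each run of adjacent called bins. For LK2_DNp63 the 10 bins each way with the largest difference from LK2_GFP that lay outside the range of the 3 other libraries of the LK2 background were taken. For Sox2 the 10 bins with most peaks in every line of one set and in no line of the other were taken, and for Brn2 the 10 bins with most Brn2 peaks that overlap a Sox2 peak in both lines. Single sites named beyond this rule were chosen after their values were seen, and the text says so.

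The interval code was tested on 50 simulated pairs of lists with 4 checks each and 0 mismatches. The limma fit was tested on data simulated from the real bins with 200 of 9148 bins changed. For set A minus set B it recovered 26% of changes of 2 on the log2 scale and 70% of changes of 4, for set A minus set C 31.5% and 81.5%, and for set B minus set C 45.5% and 90%. It also called unchanged bins: 4 and 7 beside 52 and 140 recovered ones for set A minus set B. These numbers were 5 and 16 beside 63 and 163 for set A minus set C, and 9 and 13 beside 91 and 180 for set B minus set C. Alternatives were the same number of top peaks from every list of a target (16470 for H3K27ac, 4217 for Sox2 and 1298 for Brn2), an overlap of at least 50% of the shorter peak, pseudocounts of 200 and 5000 bp, no filter, no scaling, quantile normalization, a fit of the compared sets alone, bins of 20 and 100 kb, chromosome 3 left out, each line of the compared sets or library left out in turn (lines of set C in the acetylation tests were added after the results had been seen), and LK2_GFP or LK2 as a further reference. Python 3.11.15 with numpy 2.4.6, scipy 1.17.1 and matplotlib 3.10.9, and R 4.3.3 with limma 3.58.1, were used.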

Results

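H3K27ac peaks were mapped in 13 unmodified lung squamous cell carcinoma lines, and binding sites of the transcription factors Sox2 and Brn2 in some of them. Sox2 is a factor of stem and progenitor cells that is often gained in squamous tumours, Brn2 is a POU-domain factor of neural cells, and p63 is the lineage factor of basal and squamous epithelia. The title of the series asks whether Sox2 and Brn2 together mark a class of these tumours. Set A comprised LK2 and NCI-H520 (2 lines with Sox2 and Brn2 ChIP), set B comprised HCC95, KNS62 and HCC2814 (3 lines with Sox2 ChIP), and set C comprised 8 lines with H3K27ac ChIP alone. The labels also name LK2_GFP and LK2_DNp63, derivatives of LK2, without saying how they were made. DNp63 is a common name of the p63 isoform found in basal cells, and GFP a fluorescent protein often used as a control.

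The 17 H3K27ac lists held 16470 to 43480 peaks and covered 24.6 to 73.7 Mb. LK2 had the lowest covered length of the 13 lines, with 30641 and 16470 peaks (29.1 and 24.6 Mb) in its libraries, and the libraries of NCI-H520 had 24619 and 29219 peaks (48.4 and 51.0 Mb). Set B lines had 33197 (HCC95), 41236 (KNS62) and 29473 peaks (HCC2814), and set C lines 33924 to 43480. LK2_GFP had 33454 and LK2_DNp63 30149 H3K27ac peaks. The Sox2 lists held 7611 peaks in LK2, 12048 in NCI-H520, 14048 in HCC95, 8907 in KNS62, 7511 in HCC2814, 12034 in LK2_GFP and 4217 in LK2_DNp63. Brn2 had 4819 peaks in LK2 and 1298 in NCI-H520, and p63 had 3159 peaks in LK2_DNp63. The sequencing depth was unknown for every list, so differences in the number of peaks were not read as differences in binding. Apart from H3K27ac in LK2 and NCI-H520 there was 1 library per line and target.

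Whether the lines of a set resembled each other in H3K27ac was asked first. LK2 and NCI-H520 were each other's nearest line, with a Jaccard index of 0.320, and joined the other 11 lines last in average-linkage clustering, at a mean index of 0.209. LK2 had a mean index of 0.215 and NCI-H520 of 0.221 with the other 12 lines, lower than the other lines (0.264 to 0.329). Set B lines resembled each other more closely, with a mean index of 0.407 against 0.280 for the other pairs. HARA and LC-1/SQSF of set C were nearest to HCC95 of set B (0.426 and 0.448). Repeat libraries gave an index of 0.512 in LK2 and 0.569 in NCI-H520. The index of the set A pair was not exceptional among all pairs, since 23 of 78 pairs were as large (exact p = 0.295), whereas the index within set B was reached by 4 of all groups of 3 lines (exact p = 0.0140).

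**Figure D1:**
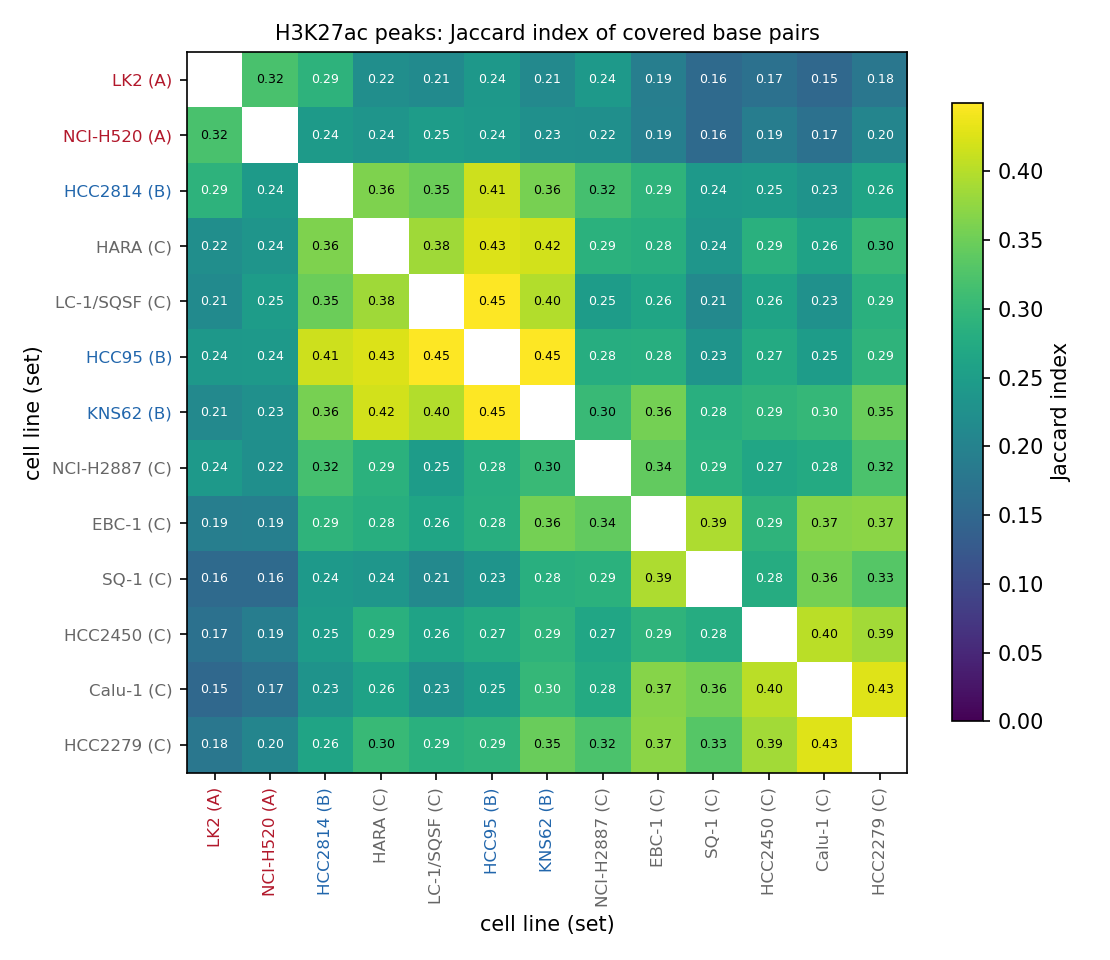
Jaccard index of H3K27ac peaks (shared over combined base pairs) for every pair of the 13 unmodified lines, with the set of each line in brackets and lines in the order of average-linkage clustering. LK2 and NCI-H520 share 0.320 with each other and at most 0.291 with any other line, while HCC95, KNS62, HCC2814, HARA and LC-1/SQSF form a block between 0.349 and 0.449.

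Regions acetylated in both set A lines and in no other line numbered 2097, and 7576 of the 114125 merged regions were acetylated in all 13 lines. Sox2 peaks of NCI-H520 lay in 53.7% (95% interval 51.6 to 55.9) of the regions of set A alone and Sox2 peaks of LK2 in 39.2% (37.2 to 41.4), against 6.91% and 4.20% of all regions. Sox2 peaks of set B lines were found in 0.763% to 2.67% of them. Brn2 peaks of LK2 lay in 19.1% (17.5 to 20.8) and Brn2 peaks of NCI-H520 in 2.53% (1.94 to 3.29), against 2.52% and 0.745% of all regions. All regions were shorter than those of set A alone (median 1367 against 2410 bp), and 57830 of them were acetylated in 1 line only. The longer regions acetylated in all 13 lines (median 3523.5 bp) held Brn2 peaks of LK2 in 12.7% and of NCI-H520 in 6.92%. Brn2 peaks of NCI-H520 were thus rarer in regions of set A alone than there. Regions acetylated in all 3 set B lines and in no other line numbered 126, a count reached by 13 of 286 groups of 3 lines (highest 644). No other pair of the 78 had as many exclusive regions as LK2 and NCI-H520 (highest other 1482). The count fell to 801, reached by 3 of 78 pairs, where both libraries of LK2 and of NCI-H520 had to hold the region, and to 1215 and 1138, reached by 2 of 78 pairs, with replicate 2 of LK2 and 1 library of every line.

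Between set A and set B, 846 of 9148 bins of 50 kb differed in covered H3K27ac length, 297 higher and 549 lower in set A (limma, adjusted p under 0.05). The bin at chromosome 18, 39250001 to 39300000, had a scaled covered length of 42.4 kb ± 7.31 (SD, n = 2 lines) in set A and none in set B or set C, a log2 difference of 5.41 (SE 0.42, limma adjusted p = 2.4e-05). Lines without covered length all take the value of the pseudocount and show no spread, which can lower the SE and adjusted p of such bins. With the compared sets alone in the fit the limma adjusted p of this bin was 0.0042. Further bins that were high in set A and had no covered length in any set B line lay at chromosome 8, 121750001 to 121800000 (log2 5.36, SE 0.46), chromosome 1, 165800001 to 165850000 (5.36, SE 0.61), chromosome 2, 130550001 to 130600000 (5.23, SE 0.42), and chromosome 6, 99250001 to 99300000 (5.07, SE 0.69). The 10 named higher bins ran from 5.07 to 5.41, and each held Sox2 peaks of NCI-H520. The size of such differences follows the pseudocount, and the same bins ran from 7.13 to 7.70 with 200 bp and from 2.92 to 3.33 with 5000 bp. The bin at chromosome 10, 95200001 to 95250000, had no covered length in set A and 21.3 kb ± 8.38 (SD, n = 3 lines) in set B, and its log2 difference was -4.40 (SE 0.39). At chromosome 17, 48100001 to 48150000, set A had 0.456 kb ± 0.645 and set B 21.1 kb ± 0.322, a log2 difference of -4.09 (SE 0.32).

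A group of lower bins lay close together on chromosome 3. The bins starting at 189100001, 189500001 and 189600001 had no covered length in set A and 17.6, 25 and 22.3 kb in set B (SD 6.65, 11.2 and 16.3, n = 3 lines), with log2 differences of -4.14 (SE 1.02), -4.62 (SE 1.36) and -4.30 (SE 1.16). Set C had 4.62, 7.82 and 8.30 kb there. Each of the 3 bins held Sox2 peaks of HCC95, KNS62 and HCC2814. Their limma adjusted p were 0.0218, 0.0497 and 0.0342, close to the threshold. With a line or library left out they rose to at most 0.156, 0.233 and 0.195, and the calls at 189100001 and 189600001 ended without LK2, NCI-H520, HCC95 or HCC2814. Over all alternatives the adjusted p ran from 0.00813 to 0.156, from 0.00727 to 0.233 and from 0.0173 to 0.195. For the bin at 189500001 the call held in 2 of 9 such fits.

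Bins higher in set A than in set B held Sox2 peaks of set A lines more often than other bins did. Sox2 peaks of NCI-H520 were present in 91.2% and those of LK2 in 76.1% of the 297 higher bins, against 33.0% and 18.6% of the 8302 bins that were not called. Brn2 peaks of LK2 were present in 53.2% of the higher bins, 8.56% of the lower bins and 16.9% of those not called. In the 549 lower bins Sox2 peaks of set B lines were the more frequent, with Sox2 peaks of HCC95 in 70.1%, of KNS62 in 60.3% and of HCC2814 in 50.3%, and those of LK2 in 12.6%. The p63 peaks of LK2_DNp63 were present in 24.8% of the lower bins, 12.8% of the higher bins and 11.5% of the bins not called. These shares describe single factor libraries and were not tested.

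Values did not overlap between the 2 set A and the 3 set B lines in 3659 of the 9148 bins, a separation that chance gives to 20% of bins, and in all 846 called bins. The count fell to 394 without LK2, 186 without NCI-H520, 537 without HCC95, 559 without KNS62 and 558 without HCC2814, to 347 with the same number of top peaks from every list and to 470 without scaling, and rose to 1768 without the filter. The share of higher bins, 35.1%, moved to 22.8% with a pseudocount of 200 bp, 54.4% with 5000 bp and 69.7% without the filter.

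Against set C, 1212 of 9148 bins differed, 512 higher and 700 lower in set A (limma). The bins at chromosome 18, 39250001, chromosome 8, 38400001, and chromosome 2, 130550001, with log2 differences of 5.41 (SE 0.36), 5.25 (SE 0.37) and 5.23 (SE 0.36), had no covered length in any of the 8 set C lines. The bin at chromosome 15, 71700001 to 71750000, reached 67.8 kb ± 20.5 (SD, n = 2 lines) in set A and 0.948 kb ± 0.826 (n = 8 lines) in set C. It held 6 Sox2 peaks in each set A line, 4 Brn2 peaks in LK2 and 1 in NCI-H520. The bin at chromosome 10, 95200001, was again lower, with 26.5 kb ± 7.20 in set C (log2 -4.74, SE 0.33), as was the bin at chromosome 7, 130550001 to 130600000 (log2 -4.39, SE 0.47). Of the 512 higher bins, 87.5% held Sox2 peaks of NCI-H520 and 47.7% held Brn2 peaks of LK2, against 31.9% and 16.4% of the bins not called.

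Values of set A and set C lines did not overlap in 1805 of the 9148 bins, a separation that chance gives to 4.44% of bins, and in 1119 of the 1212 called bins. The share of higher bins, 42.2%, moved to 17.5% without scaling to equal covered length, 28.8% with a pseudocount of 200 bp, 64.5% with 5000 bp and 74.4% without the filter. The median log2 difference over all bins was -0.15 with scaling and -0.66 without it for set A minus set C, and -0.21 and -0.51 for set A minus set B, and differences are reported after scaling. The count was 477 without LK2, 306 without NCI-H520, 487 with the same number of top peaks and 2189 without the filter. Set A against all 11 other lines gave 1104 bins, 460 higher and 644 lower, and no other pair of lines gave more than 2 bins in the same fit.

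Between set B and set C, limma called 0 of 9148 bins, and 1079 bins had an unadjusted p under 0.05. No other tool was run. Values did not overlap between the 2 sets in 180 bins, a separation that chance gives to 1.21% of bins. The count was 46 without LC-1/SQSF, 10 without HARA and 2 without KNS62, and 34 without the filter.

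Sox2 sites also differed between the sets. The Jaccard index of Sox2 peaks was 0.153 for LK2 with NCI-H520 and 0.139 to 0.181 within set B, against 0.0381 to 0.0619 between the sets. Of 35819 merged Sox2 sites, 283 were found in all 5 lines and 25975 in 1 line. Sites of both set A lines and no set B line numbered 1962, and sites of all 3 set B lines and no set A line numbered 1124. In set A the bins with most exclusive Sox2 peaks lay at chromosome 8, 121750001 to 121800000 (4 peaks in LK2 and 5 in NCI-H520), chromosome 14, 79300001 to 79350000 (4 and 5), and chromosome 7, 139300001 to 139350000 (3 and 6). In set B they lay at chromosome 3, 190050001 to 190100000 (6, 4 and 3 peaks in HCC95, KNS62 and HCC2814), chromosome 3, 189600001 to 189650000 (4, 1 and 7), and chromosome 20, 52400001 to 52450000 (5, 4 and 2), and 5 of the 10 named bins of set B were on chromosome 3.

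The mean index was 0.156 within sets and 0.0544 between them, the largest gap of the 10 possible splits (exact p = 0.1, the smallest that this design allows). The highest counts among the other splits were 1452 sites for a pair and 215 for the remaining 3 lines. With the same number of top peaks the counts were 912 and 442, and with LK2_GFP in place of LK2 the count for set A was 3008. Leaving out a line raises such counts by construction, to at most 9611 for set A and 2574 for set B.

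Brn2 and Sox2 peaks were then compared within each set A line. In LK2, 1923 of 4819 Brn2 sites (39.9%, 95% interval 38.5 to 41.3) overlapped a Sox2 peak of LK2, above the 11.5% (11.2 to 11.9) of LK2 H3K27ac peaks that did. In NCI-H520, 236 of 1298 Brn2 sites (18.2%, 16.2 to 20.4) overlapped a Sox2 peak of NCI-H520, below the 24.4% (23.9 to 25) of its H3K27ac peaks. H3K27ac peaks were wider than Brn2 peaks, with median lengths of 731 against 335 bp in LK2 and 1329 against 235 bp in NCI-H520, and wide peaks overlap others more often. Cut to the median Brn2 length at their centres, 7.07% (6.78 to 7.36) of LK2 and 12.2% (11.8 to 12.7) of NCI-H520 H3K27ac peaks overlapped Sox2, below the Brn2 share of either line. Circular shifts gave means of 0.317% and 0.334%, so both shares lay far above random placement. Of the NCI-H520 Brn2 sites 53.2% were Brn2 sites of LK2. Brn2 sites common to both lines numbered 643, of which 48 carried Sox2 in both lines and 31 of these in no set B line. With equal numbers of top peaks the share in NCI-H520 was 10.5%.

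The bins with most Brn2 sites that overlapped Sox2 in both lines lay at chromosome 3, 185750001 to 185800000 (4 in LK2 and 1 in NCI-H520), chromosome 3, 177300001 to 177350000 (2 and 2), and chromosome 1, 45950001 to 46000000 (1 and 3), out of 59 bins with any. Among the single sites with both factors in both lines and no Sox2 peak in set B were chromosome 6, 99250238 to 99250869, and chromosome 8, 121787373 to 121787877, which lie in named bins higher in set A and were chosen after their values were seen. Both were acetylated in 2 of the 13 lines. NCI-H520 Brn2 sites lay in regions acetylated in all 13 lines in 45.3% of cases (42.6 to 48.0) and LK2 Brn2 sites in 28.4% (27.2 to 29.7), against 12.6% and 5.91% of the Sox2 sites of the same lines. Of equally many top LK2 Brn2 sites, 48.5% (45.7 to 51.2) lay there, with an interval that overlaps that of NCI-H520.

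H3K27ac at factor sites differed between the sets. LK2 Sox2 sites were acetylated in 32.4% ± 0.0697 of cases in set A (SD, n = 2 lines), 16.0% ± 3.56 in set B (n = 3) and 14.1% ± 1.93 in set C (n = 8). Relative to the share of all H3K27ac regions acetylated in a line, LK2 Brn2 sites had a ratio of 2.73 ± 0.373 in set A and 1.36 ± 0.168 in the 11 other lines, and NCI-H520 Brn2 sites 3.25 ± 0.0544 and 2.01 ± 0.288. At LK2 Brn2 sites the mean shares themselves lay relatively closer, at 46.6% in set A, 35.7% in set B and 34.4% in set C. The p63 sites of LK2_DNp63 had a ratio of 1.90 ± 0.171 in set B and 0.887 ± 0.525 in set C, with 47.2% ± 12.2 of sites acetylated in set B, 23.3% ± 13.9 in set C and 19.5% ± 0.235 in set A. Within set C, p63 sites were acetylated in 46.5% of cases in LC-1/SQSF and 45.1% in HARA, and in 12.3% to 18.1% in the other lines.

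**Figure D2:**
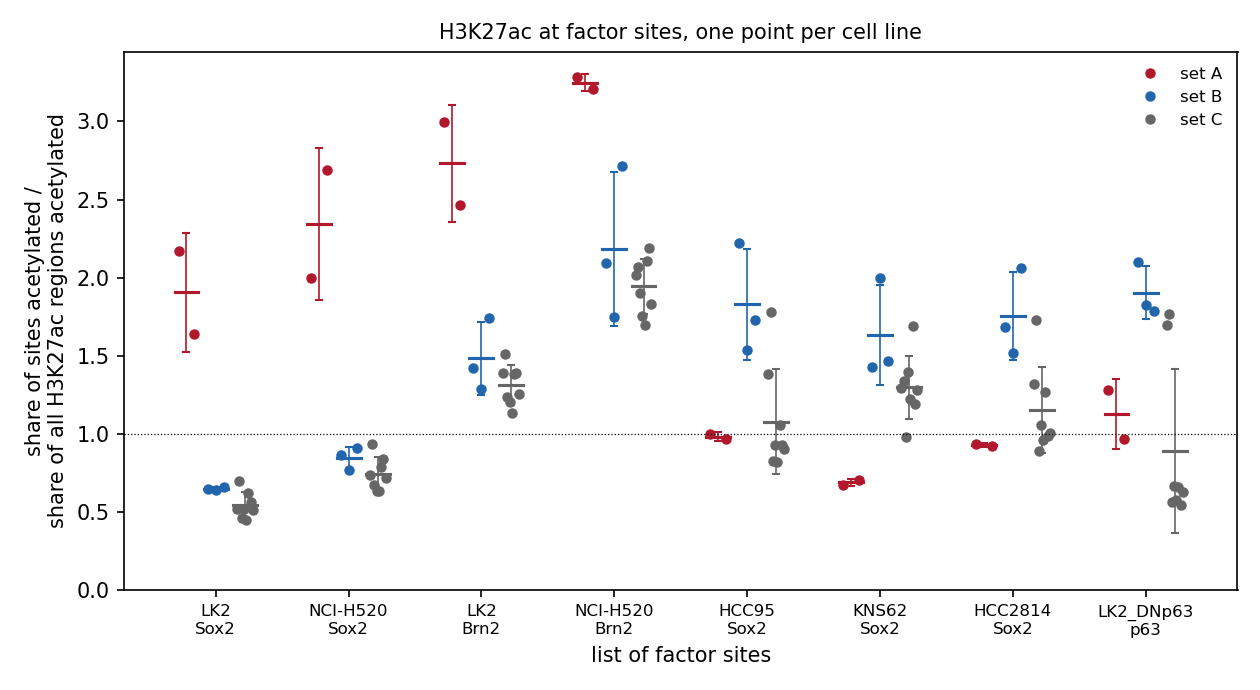
Share of the sites of each factor list that are acetylated in a line, divided by the share of all merged H3K27ac regions acetylated in that line (no unit), with 1 point per line, bars at the mean and whiskers of 1 SD for set A (n = 2), set B (n = 3) and set C (n = 8), and a dotted line at 1. Sox2 and Brn2 sites of LK2 and NCI-H520 have their highest ratios in both set A lines, and p63 sites have a ratio of 1.90 ± 0.171 in set B and 0.887 ± 0.525 in set C.

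The ratios of Sox2 sites of LK2, NCI-H520, LK2_GFP and LK2_DNp63 and of Brn2 sites of LK2 and NCI-H520 were higher in both set A lines than in each of the 11 others (exact permutation p = 0.0128, the smallest possible, adjusted 0.0321). At NCI-H520 Brn2 sites the difference in ratio fell from 1.24 to 0.779 with the same number of top peaks (exact p = 0.0385), so set A was then not the most extreme pair. The shares themselves overlapped at these sites, at 49.1% in LK2 and 63.9% in NCI-H520 against 50.5% to 52.9% in set B and 42.8% to 54.3% in set C, so the separation there rests on the lower share of all regions acetylated in set A. KNS62 Sox2 sites had a lower ratio in set A (0.688 ± 0.0224 against 1.39 ± 0.270, exact p = 0.0128, adjusted 0.0321). Between set B and set C, the ratio at p63 sites was higher in 3 of 3 set B lines than in every set C line (exact p = 0.00606, adjusted 0.0321), whereas the shares themselves overlapped, with a lowest value of 33.1% in set B and a highest of 46.5% in set C. For this ratio the exact p was 0.0182 with the same number of top peaks and 0.0242 with an overlap of at least 50% of the shorter peak. Mean ratios of HCC95, HCC2814 and LK2_DNp63 Sox2 sites were also higher in set B (exact p = 0.0182, adjusted 0.0331), with 1 of 3 lines above every set C line, whereas KNS62 Sox2 sites did not pass (exact p = 0.0545, adjusted 0.0909). A list taken from a line is compared with the acetylation of that same line, which favours its own set. With LK2 or NCI-H520 left out the smallest possible exact p was 0.0833, the HCC95 comparison had an exact p of 0.0667 without HCC95, and the HCC2814 comparison 0.0667 without HCC2814 and 0.0727 with an overlap of at least 50% of the shorter peak. The KNS62 comparison had an exact p of 0.0444 without HCC95 or without HCC2814 and of 0.00833 without EBC-1.

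Sox2 sites and acetylation of LK2_DNp63 were compared with those of LK2_GFP. Of the 4217 Sox2 peaks of LK2_DNp63, 3476 were kept from LK2_GFP and 741 gained, and 8516 of the 12034 LK2_GFP peaks were lost. The median LK2_GFP score was 75.6 at lost and 157 at kept sites. The median LK2_DNp63 score was 63.6 at gained and 80.3 at kept sites, and scores were not compared between the lists. A p63 peak lay at 15.9% (95% interval 13.5 to 18.7) of gained, 5.26% (4.57 to 6.06) of kept and 1.70% (1.45 to 2.0) of lost Sox2 sites. In numbers these were 118 gained, 183 kept and 145 lost sites, so more Sox2 sites with p63 were lost than gained. Of the 3159 p63 sites, 10.3% overlapped a Sox2 peak of LK2_GFP and 9.56% one of LK2_DNp63. The H3K27ac peaks of these libraries did so in 20.8% and 8.31% of cases. With the 4217 top LK2_GFP Sox2 peaks the share of p63 sites was 4.24%. Gained sites were Sox2 sites of HCC95, KNS62 and HCC2814 in 23.5%, 16.1% and 23.6% of cases, and kept sites in 27.2%, 21.2% and 25% of cases. Sox2 peaks of NCI-H520 lay at 4.05% (2.85 to 5.72) of gained and 43.2% (41.6 to 44.9) of kept sites. Brn2 peaks of LK2 lay at 33.9% of kept, 12.8% of lost and 2.56% of gained sites. As a measure of the spread between libraries, 54.0% of LK2_GFP Sox2 peaks were found in LK2 and 29.2% in LK2_DNp63. Of the lost sites, 42.3% were Sox2 sites of LK2. In the other direction, 86.0% of LK2 and 82.4% of LK2_DNp63 Sox2 peaks were found in LK2_GFP. With the 4217 top peaks of each list these shares were 72.8% and 57.1%, with 1810 gained and 1801 lost sites, and p63 at 10.7% of the gained sites.

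In H3K27ac, 22120 of 30149 peaks of LK2_DNp63 were kept and 8029 gained, and 8851 peaks of LK2_GFP were lost. Of the LK2_DNp63 peaks 26.6% were absent from LK2_GFP, against 24.2% and 11.9% in replicates 1 and 2 of LK2. LK2_DNp63 lacked 26.5% of the LK2_GFP peaks, whereas the LK2 libraries lacked 31.5% and 50.9%. The share of lost peaks was thus no larger than between libraries without DNp63. A p63 peak lay at 9.55% (8.93 to 10.2) of gained, 4.17% (3.92 to 4.44) of kept and 1.36% (1.14 to 1.62) of lost regions. H3K27ac peaks of the LK2 libraries that were absent from LK2_GFP had a p63 peak in 0.973% and 1.38% of cases. The share of p63 sites that were acetylated was 29.3% (27.8 to 31.0) in LK2_GFP and 47.7% (46.0 to 49.4) in LK2_DNp63, and 23.3% and 16.0% in the LK2 libraries. The only p63 list comes from LK2_DNp63, which favours the acetylation of that arm. Gained regions were acetylated in 35.3% ± 7.08 of cases in set B (SD, n = 3 lines), 26.6% ± 7.50 in set C (n = 8) and 16.8% in NCI-H520, whereas lost regions were acetylated in 20.5% ± 7.19, 19.9% ± 5.75 and 39.6%. LK2 peaks absent from LK2_GFP had 22.1%, 19.3% and 38.5% in replicate 1, and 15.3%, 13.7% and 50.6% in replicate 2. The higher share of lost regions in NCI-H520 was therefore not particular to peaks lost in LK2_DNp63. With an overlap of at least 50% of the shorter peak the p63 shares were 5.45% for gained, 3.42% for kept and 1.06% for lost regions, and with equal numbers of top peaks the share of lost regions was 3.11%.

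**Figure D3:**
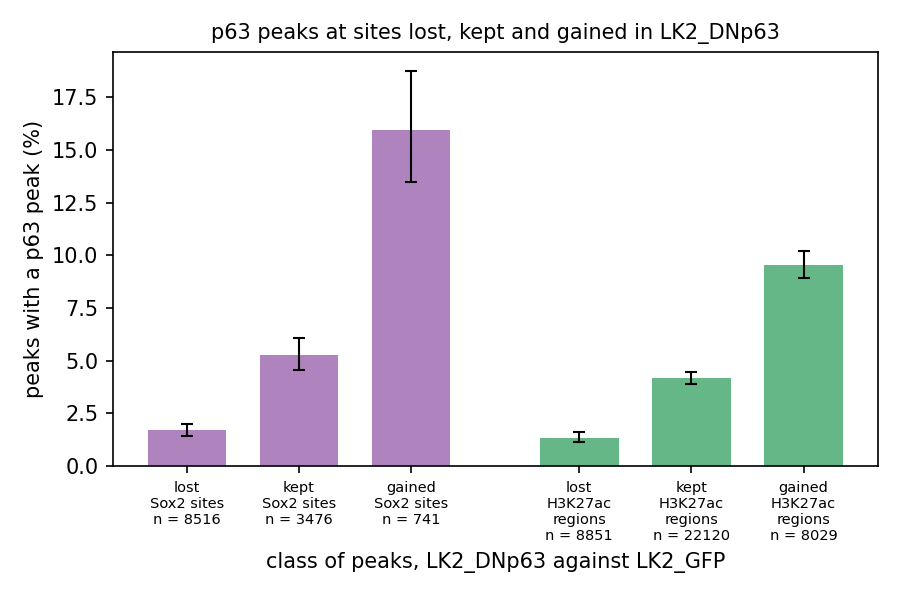
Percentage of Sox2 sites (purple) and H3K27ac regions (green) with a p63 peak among peaks lost, kept and gained in LK2_DNp63 against LK2_GFP, with Wilson 95% intervals as error bars, n the number of peaks and 1 library per arm. The share is lowest for lost and highest for gained peaks in both, at 1.70%, 5.26% and 15.9% for Sox2 and 1.36%, 4.17% and 9.55% for H3K27ac. For Sox2 these are 145 lost, 183 kept and 118 gained sites with a p63 peak.

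Bins that differed between set A and set B were then followed in LK2_DNp63. In the 297 bins higher in set A the mean log2 difference between LK2_DNp63 and LK2_GFP was -0.68, below the lowest of 10000 random lists of bins matched on covered length (-0.39), and 252 bins had a lower and 35 a higher value. In the 549 bins lower in set A the mean was 0.38, above the highest random list (0.24). LK2 took part in the choice of these bins. Without LK2, 186 bins were called higher and 208 lower in NCI-H520 than in set B, in a fit with 1 line in set A whose spread came from sets B and C alone, and the means there were -0.49 and 0.39, outside random lists matched on the mean length of both arms (-0.15 to 0.12 and -0.09 to 0.19). The bin at chromosome 14, 79300001 to 79350000, had 17.5 kb in LK2_GFP, 39.8 kb in NCI-H520 and none in LK2_DNp63, set B or set C (log2 -4.21). At chromosome 18, 37650001 to 37700000, the length was 14.7 kb in LK2_GFP and 1.02 kb in LK2_DNp63 (log2 -2.95). At chromosome 8, 49600001 to 49650000, it was 1.26 kb in LK2_GFP, 10.4 kb in LK2_DNp63 (log2 2.34) and 12.5 kb ± 4.55 in set B (SD, n = 3 lines), and this bin held 5 p63 and 3 Sox2 peaks of LK2_DNp63. Other named bins did not share this pattern. The largest rise, at chromosome 8, 134100001 (log2 3.89), had no factor peak and no covered length in set B. A rise at chromosome 1, 219900001 (log2 2.62), had 37.0 kb in NCI-H520 and 0.503 kb in set B. The fall at chromosome 1, 199100001 (log2 -3.20), had none in NCI-H520. With 1 library per arm these differences have no replicate check and no p-value between the arms, and the random lists compare bins, not libraries. The LK2 libraries had means of 0.27 and 0.68 against LK2_GFP in the 297 bins, and of 0.20 and 0.47 in the 186 bins called without LK2. In the lower bins they were -0.03 and -0.34 in the 549, and 0.01 and -0.26 in the 208. Over the 4941 bins measured in this background, 1021 lay above and 1705 below the 3 other libraries for LK2_DNp63, while replicate 2 of LK2 in the same position gave 2263 and 996. By a log2 difference of over 1, 63 lay above and 213 below for LK2_DNp63, against 27 and 95 for replicate 2 of LK2, 1 and 19 for replicate 1, and 8 and 5 for LK2_GFP.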

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

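The test of whether lost Sox2 sites kept H3K27ac and the comparison with H3K27ac peaks cut to the length of Brn2 peaks were chosen after the results were seen, and the fits over bins for every pair of lines and the equal top lists of LK2, LK2_GFP and LK2_DNp63 were added after the lists had been seen. The fits with 1 library per line and with equal numbers of top peaks were written down before their counts over pairs were known, but after related counts for set A minus set B had been seen.

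In set C, SQ-1 lay below the 7 other lines in the share of NCI-H520 Brn2 sites that were acetylated, at 42.8%. LC-1/SQSF lay above the others at the Sox2 sites of LK2 (18.3%), LK2_GFP (21.9%) and LK2_DNp63 (22.5%). The last 3 lists share many sites, so they are not independent, and 26 extremes of 13 measures were examined where chance marks about 1 in 20 groups.

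The share of Brn2 sites with a Sox2 peak was 39.9% in LK2 and 18.2% in NCI-H520, at 28.4 and -6.23 percentage points from the share of the line's H3K27ac peaks, and the difference between the lines was not tested. The opposite signs depended on peak width: with H3K27ac peaks cut to the median Brn2 length, the background was 7.07% in LK2 and 12.2% in NCI-H520 at peak centres, and 7.09% and 8.03% at random places in the peaks, so both lines lay above it. The short NCI-H520 list is not the whole source, because the 1298 top LK2 Brn2 peaks still had a Sox2 share of 37.1%. Regions acetylated in every line may account for part of the gap, since they held 45.3% of NCI-H520 and 28.4% of LK2 Brn2 sites, and the Sox2 share in NCI-H520 was 21.8% outside and 13.8% inside them, as this explanation predicted. As the whole source it is argued against by a comparison added after these values were seen: outside those regions the share was still 21.8% in NCI-H520 against 53.3% in LK2, and the top LK2 peaks had a like share in such regions (48.5%). Inside those regions the Sox2 share was 6.06% in LK2, below the 13.8% in NCI-H520, so the gap lay outside them only. A difference between the lines in where Brn2 binds and a weaker single NCI-H520 Brn2 library both stay open.

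LK2 and NCI-H520 differed from the 11 other lines in 1104 bins, and no other pair of the 78 reached that count (1 of 78, highest other 2). This is the most extreme rank that 78 pairs allow, so it argues against chance but cannot exclude it. Every other pair leaves LK2, NCI-H520 or both among the remaining lines, which can widen the spread and lower its count. Having 2 libraries for these lines is argued against by the fits with 1 library of every line, which gave 994 and 1244 bins (highest other pair 4 and 16). The short lists of both lines are argued against by equal numbers of top peaks, which left 465 bins (highest other 98), although the count was then less than 50% of 1104, so list length may add to it. A biological difference of these lines, such as the activity of Sox2 and Brn2, remains a hypothesis, since which lines received Brn2 ChIP was chosen by the authors and copy number was examined only by leaving out chromosome 3 (789 bins for set A minus set B).

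LK2_DNp63 listed 4217 Sox2 peaks and LK2_GFP 12034. Lost sites were the weaker LK2_GFP peaks (median score 75.6, against 157 for kept sites), as a less sensitive library would give. Among equal top lists LK2_DNp63 lay 15.8 percentage points below LK2 in the share found in LK2_GFP. That set the whole LK2_DNp63 list against the stronger part of the 7611 LK2 peaks, so the bound written for this test was unsuited and the test leaves lower sensitivity open. As the whole source, lower sensitivity would miss sites that did not change, and their acetylation bears on this. Sites that lost Sox2 kept acetylation less often, by over 5 points, than sites that held Sox2 in 5 of 5 classes of score (64.7% against 79.0% over all classes). Lost and kept sites were, however, sorted by a Sox2 library of the same cells, and a less sensitive library may keep the sites most active there. The comparison therefore cannot separate lower sensitivity from a loss of Sox2. Libraries can also differ by more than those 5 points, so the bound alone decides nothing. In LK2 the lost sites were acetylated more often in the 4 lower classes, at 76.9% against 53.4% in the lowest, the opposite direction. In the class of highest scores the shares were 48.6% (95% interval 43.3 to 54.0) against 78.1% (75.5 to 80.5) in LK2_DNp63 and 80.2% against 80.3% in LK2. The gained sites carried p63 in 15.9% of cases, above the 5.26% of kept sites (10.7% and 4.49% with equal top lists), which is an overlap of single libraries and shows no mechanism. Part of the loss may be technical, and with 1 library per arm how much stays open.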

How the results depend on the processing

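Of 259 alternatives of the results that answer a comparison, 197 stayed the same, 48 moved, 11 lost and 3 gained significance, and 0 reversed. A test stayed the same if it kept its direction and its side of the threshold. A count had to stay within a fixed ratio of the main count, a share of peaks within its Wilson interval, and the Sox2 index within the spread. Counts and shares could only stay or move, so for them no reversal was possible. The bins, bin sizes, fits without chromosome 3, fits with 1 library per line, the requirement of both libraries and the acetylation tests without a line of set C were chosen after seeing the data. Gene windows, gene lists, motif shares, distances to transcription starts, 1 gene per locus and estimated correlations were not run, for want of an annotation of the build. No paired analysis was possible because replicate numbers exist only for H3K27ac of LK2 and NCI-H520, whose libraries were averaged. Depth is unknown, so it limits every count of peaks to an unknown degree. Unless a construction is named, the cause was not tested.

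With the same number of top peaks from every list (fewer peaks by construction), bins were 347 for set A minus set B, 487 for A minus C, 2 for B minus C and 465 for A against all others. Sox2 sites of set A alone were 912 and of set B alone 442. The set A difference in acetylation ratio at NCI-H520 Brn2 sites was 0.779 (exact p = 0.0385), against 1.24. Brn2 sites with Sox2 were 32.1% in LK2 and 10.5% in NCI-H520. In LK2_DNp63, Sox2 sites gained and lost were 1810 and 1801, with p63 at 10.7% of gained and 4.49% of kept sites. H3K27ac regions were 12907 kept, 3563 gained and 2829 lost, with p63 at 11.8% of gained and 3.11% of lost regions. Without the filter, bins were 1768, 2189 and 34 for A minus B, A minus C and B minus C. A minus B gave 470 without scaling, and B minus C gave 4 with a pseudocount of 200 bp, 1 with 5000 bp and 3 with the compared sets alone. Regions of set A alone were 801 with both libraries needed and 1215 and 1138 with replicate 2 of LK2 and 1 library per line. The Sox2 gap within minus between sets was 0.116 by peaks, against 0.101 by base pairs. Sox2 sites of set A alone were 3008 with LK2_GFP in place of LK2.

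With an overlap of at least 50% of the shorter peak, the set B minus C ratio at HCC2814 Sox2 sites was 0.377 (exact p = 0.0727, over all its alternatives 0.00833 to 0.0727), and p63 lay at 5.45% of gained, 3.42% of kept and 1.06% of lost H3K27ac regions. This overlap cannot change counts of sites over the merged union. With LK2 added to the reference, p63 lay at 10.9% of gained H3K27ac regions.

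Leaving out a line or library gave 186 to 1088 bins for A minus B, 306 to 1623 for A minus C and 0 to 46 for B minus C. A minus B fell most without NCI-H520 (186) and LK2 (394), and B minus C rose most without LC-1/SQSF (46). Sox2 sites ranged from 2058 to 9611 for set A alone and 1257 to 2574 for set B alone, by construction. Differences in acetylation ratio ranged from 1.11 to 1.64 at LK2 Brn2, 1.20 to 1.31 at NCI-H520 Brn2, 1.07 to 1.60 at LK2 Sox2 and 1.23 to 1.92 at NCI-H520 Sox2 sites for set A, where 1 remaining line allows no exact p under 0.0833. For set B minus C they ranged from 0.918 to 1.14 at p63, 0.556 to 0.900 at HCC95, 0.147 to 0.433 at KNS62 and 0.448 to 0.722 at HCC2814 Sox2 sites. Of the tests without a line of set C, 1 changed a call, at KNS62 Sox2 sites without EBC-1 (exact p = 0.00833). The 40 named bins, counted per comparison although several were named in both, kept their direction in all 776 alternatives in which they were tested. They were chosen for lines that did not overlap between the sets, so few alternatives could have reversed them and this count shows little. Of the 776 calls 35 were lost. The size of the 10 higher ones of set A minus set B ran from 7.13 to 7.70 with a pseudocount of 200 bp and from 2.92 to 3.33 with 5000 bp. The named bins of LK2_DNp63 kept their direction in 80 of 80, but they were chosen for lying outside the range of the 3 other libraries. Their direction therefore shows little as well. The size of the latter differences moved in each of the 80, and with 1 library per arm there was no spread to judge it by. Bins called without LK2, with 1 line in set A and the spread from sets B and C alone, had a mean difference between LK2_DNp63 and LK2_GFP of -0.49 where NCI-H520 was higher and 0.39 where it was lower, against -0.68 and 0.38 with LK2.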

Other observations

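The ranking of the set A pair and the splits of set B and set C were planned, but the bound for the ranking was written and the splits by unadjusted p were added after values were seen, and the bins and the index without chromosome 3 were chosen after the lists had been seen.

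HARA and LC-1/SQSF, which have no Sox2 list here, lay close to set B in several measures. Their mean Jaccard index of H3K27ac with the set B lines was 0.402 and 0.398, against 0.252 to 0.310 for the 6 other lines of set C, and p63 sites were acetylated in 45.1% and 46.5% of cases. HCC95 Sox2 sites were acetylated in 46.7% of cases in LC-1/SQSF and 36.7% in HARA, and in 45.0% ± 12.1 in set B (SD, n = 3 lines). Set B against set C gave 0 bins, a count that 100 of 100 drawn splits of the 11 lines reach by definition, so it decides nothing about chance. Bins with an unadjusted p under 0.05 numbered 1079, reached by 8 of 100 splits (highest other 1967), so chance cannot be excluded for them. Of the 100 splits, whose median was 0 called bins, HCC95, HCC2814 and LC-1/SQSF against the rest gave the most, 326, which points to a structure of the samples that was not tested.

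The similarity of LK2 with NCI-H520 in H3K27ac was reached by 23 of 78 pairs of lines (highest 0.449), so chance cannot be excluded for the index itself. The 23 include the pair itself. It was 21 of 78 with the same number of top peaks and 24 of 78 without chromosome 3.

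Sox2 sites gained in LK2_DNp63 were acetylated in LK2_DNp63 in 36.0% of cases and in LK2_GFP in 15.7%, where sites called in LK2_DNp63 favour the acetylation of that arm. The gained Sox2 site with the highest p63 score lay at chromosome 5, 137840157 to 137841300, and was a Sox2 site of all 3 set B lines. This site and those named next were chosen after their values were seen. Gained sites at chromosome 8, 49616336 to 49617518 and 49621228 to 49622287, lay in a bin whose covered H3K27ac length rose from 1.26 to 10.4 kb, and both were Sox2 sites of 2 set B lines. The H3K27ac index of LK2_DNp63 with set B lines exceeded that of LK2_GFP by 0.0325 to 0.0387. With the 8 set C lines it did so by 0.00789 to 0.0321 (0.0321 in LC-1/SQSF and 0.0300 in HARA). The difference was -0.0330 with NCI-H520 and -0.0751 with LK2 itself, the largest change, so the fall was not particular to NCI-H520. The index depends on covered length, which was 36.6 Mb in LK2_DNp63 and 33.8 Mb in LK2_GFP. Whether the differences hold at equal list length was not tested, and each arm had 1 library.

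HARA and LC-1/SQSF shared a code in the sample descriptions and had an index of 0.385, reached by 18 of 136 pairs of libraries. Calu-1 and EBC-1 shared a different code and had 0.367, reached by 21 of 136. Replicate 1 of NCI-H520 and SQ-1 shared another code and had 0.150, against 0.163 for replicate 2 of NCI-H520, which did not share it.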
